A study of Caenorhabditis elegans with 6 samples.

How the data were processed

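RNA sequencing of whole N2 worms gave 6 libraries, 3 from control worms and 3 from worms given 10 µM of the agent that the labels call Forsythia. The labels describe poly(A)-selected libraries of RNA with an integrity number above 7. The deposited gene table holds read counts per gene and library, per the file headers, as whole numbers with no normalization. It also holds FPKM per gene and library, per the file headers, which the authors computed from the counts: for genes of at least 300 counts, count divided by FPKM equalled 1 factor per library times 1 length per gene within 0.54%. The submitters' processing notes name CASAVA 1.4 and the mouse builds mm9 and mm10, which do not match a worm gene table. The aligner, the counting program, the handling of strand and of reads shared between genes, and the annotation release are not given in the sources used here. The table lists 21798 genes, of which 21793 were matched by gene ID to the RefSeq annotation of WBcel235, and 96.6% of their starts and 95.4% of their ends were identical, so coordinates are those of the table, in WBcel235. Genes with no read in any of the 6 libraries are not listed in the table.

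The main test was edgeR's quasi-likelihood test on the counts, two-sided, with TMM scaling, after filterByExpr with a minimum count of 10 and a minimum total of 15 left 15042 genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and counted again at an absolute log2 fold change of at least 1. The comparison, its tests, the 41 gene lists, the rule for naming genes and most alternatives were set before the data were examined. That plan named limma on log2(FPKM + 1) as the test for a table of FPKM alone and edgeR for a table with counts. As counts were present, limma became the alternative, over 11146 genes with a mean of at least 1 FPKM. Log2 fold changes are Forsythia minus control, with their standard error from the edgeR fit. CPM are counts scaled to TMM library sizes. In 10 tested genes all libraries of 1 group had no count, and no fold change is printed for these. List medians with such genes set to a floor of 3 counts per library were identical. Library depths between 51602227 and 63554179 counts leave little counting error in genes of moderate expression, so the spread between libraries sets the precision: chi-square per degree of freedom between pairs of libraries ran from 10.5 to 484.

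Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 41 lists, and again with an estimated correlation and with fry. Members were counted at the adjusted p over all genes, and with p adjusted over the list alone. The genes named are the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap and whose higher group reached a mean of 5 FPKM and 20 counts, the 2 members with the smallest p of each list past camera, the 1 such member of other lists where it was called, and 20 stress and immune genes fixed in the plan. Members outside this rule that are named to complete a small count were chosen after their values were seen. Alternatives covered pseudocounts, filters, scaling, variance models, a block for replicate number, DESeq2, and leaving out each library in turn. The labels give no batch. Tested on simulated data of the same size, with 200 of 15042 genes changed, the main test recovered 37% of changes of 1 and 80% of changes of 2 on the log2 scale, with 13 false calls. That simulation gave both groups the same spread. On simulated data with the unequal spread of these groups and no change, edgeR called 0 genes and DESeq2 35. Genes were simulated independently, so neither simulation shows what spread shared between genes, as among these controls, does to the calls. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.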

Results

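RNA of whole *Caenorhabditis elegans* of the N2 strain, the usual laboratory wild type, was sequenced in 6 libraries: 3 from control worms and 3 from worms exposed to 10 µM of an agent that the labels call Forsythia. The title of the series names a glycoside of *Forsythia suspensa*, a shrub used in traditional Chinese medicine, and asks whether it promotes innate immunity by way of endoplasmic reticulum (ER) stress. The design text adds a test of immunity on *Pseudomonas aeruginosa*, a bacterium that infects the worm's intestine. Whether the sequenced worms had met the bacterium, and their age or stage, are not given in the sources used here. Gene counts summed to 59401747, 63554179 and 56900294 in the control libraries of replicates 1, 2 and 3, and to 57138625, 61608488 and 51602227 in the treated ones. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

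The treated libraries resembled each other closely and the controls did not. Pearson's r of log2(FPKM + 1) across genes, which are not independent replicates, was 0.996 for each treated pair, but 0.943, 0.974 and 0.989 for the control pairs 1 and 2, 1 and 3, and 2 and 3. The biological coefficient of variation over all tested genes was 36.9% among controls and 8.90% among treated libraries. Controls 1 and 2 lay farthest apart, with median log2 differences (control 2 minus control 1) of -2.55 over 62 sperm genes, -1.26 over 142 cuticle collagen genes and 1.16 over 7 vitellogenin and yolk receptor genes. Vitellogenins, the yolk proteins made in the intestine, took 1.99%, 4.63% and 3.67% of control counts and 5.45%, 5.78% and 6.11% of treated counts. Ribosomal RNA took between 2.04% and 4.99% of counts.

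**Figure D1:**
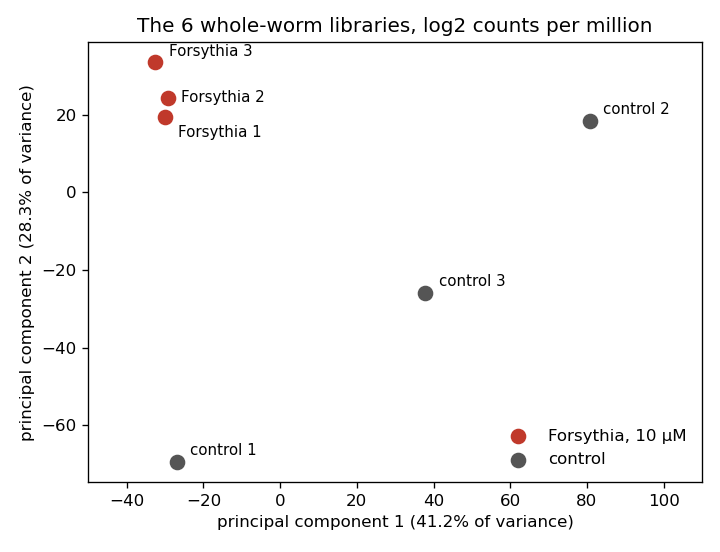
Principal components 1 (x axis, 41.2% of variance) and 2 (y axis, 28.3%) of log2 CPM over 15042 tested genes, with 1 point per library. The 3 treated libraries sit together at about -30 on the first axis and 19 to 33 on the second, and the 3 controls are spread out, from control 1 at -26.9 and -69.4 to control 2 at 80.8 and 18.4.

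In worms exposed to Forsythia, 15 of 126 C-type lectin genes rose and 7 fell, and 3 of 13 lysozyme genes, 5 of 37 genes of ABC efflux pumps and 2 of 7 genes of the vitellogenin list rose with 0 falling. Of 23 cytosolic heat shock genes 6 fell and 0 rose, but all of the 6 except *bag-1* have near-identical copies that can share reads. As lists these passed camera with its preset correlation, and none did with an estimated correlation (adjusted p = 0.082, 0.11, 0.082, 0.47 and 0.082). The ER chaperone *hsp-4*, the usual marker of ER stress in the worm, did not pass the test, at 194 ± 56.4 in controls and 185 ± 4.75 in treated libraries (CPM, mean ± SD, n = 3 per group, as throughout). Of 15042 genes tested with edgeR's quasi-likelihood test, 1128 passed a Benjamini-Hochberg adjusted p of 0.05: 489 rose and 639 fell, so 43.4% of them rose. Of these, 408 changed by a log2 fold change of at least 1, with 95 rises and 313 falls. In all 1128 genes the treated libraries lay wholly above or wholly below the controls, as they did in 4812 or 32% of the genes tested. Chance gives 10% only where both groups have the same spread, and more where 1 group is tighter, as here. No excess over chance is therefore read from this share. The split depended on the scaling. With limma on the deposited FPKM values 304 rose and 1114 fell (21.4% higher), and with size factors of FPKM 686 rose and 698 fell (49.6% higher). The median log2 fold change of all genes was -0.04 in the main test and -0.14 on FPKM.

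The count changed widely when 1 library was left out, and how much of this was lost power was not tested. Without control replicate 1 edgeR called 4619 genes, and without control replicate 2 it called 2136. Without control replicate 3, or without Forsythia replicate 1, 2 or 3, it called 0, with 2494, 2651, 2389 and 2372 genes at an unadjusted p under 0.05, and DESeq2 then called 965, 1090, 909 and 891. In each of these 6 tests with edgeR all 1128 genes kept the sign of their change. Gene lists moved with these counts: without control replicate 1, 40 of the 41 lists had over 1.5 times as many called genes, and without control replicate 2, 21 did. A gene that passed with all 6 libraries, in any paragraph here, therefore did not pass edgeR's test in those 4 smaller sets. DESeq2 called 2136 genes with all 6 libraries, 1120 of them among the 1128.

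**Figure D2:**
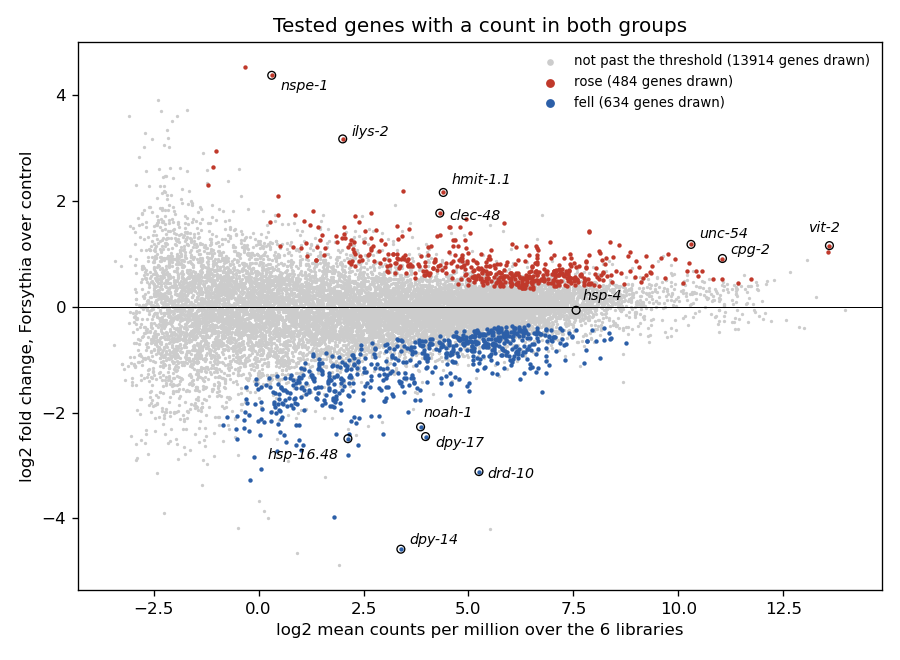
Log2 fold change, Forsythia over control (y axis), against the log2 mean CPM over the 6 libraries (x axis), 1 point per tested gene with a count in both groups; 10 tested genes without a count in a group are not drawn. Red points rose and blue points fell at an adjusted p under 0.05 (edgeR). *vit-2* rose by 1.16 among the most abundant genes, *dpy-14* lay at -4.58, and *hsp-4* at -0.07.

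Among genes that passed with a mean of at least 5 FPKM in the higher group, the largest rises were those of *nspe-2* and *nspe-1*, neighbouring genes of nematode-specific peptides (chromosome II, 12619173 to 12619388, minus strand, and 12620649 to 12620864, WBcel235). *nspe-1* stood at 0.112 ± 0.0591 in controls and 2.37 ± 0.154 in treated libraries (log2 fold change 4.38, SE 0.42, adjusted p = 0.0069), and *nspe-2* at 0.0646 ± 0.0446 against 1.53 ± 0.397 CPM (log2 fold change 4.53, SE 0.56, adjusted p = 0.010). They are near-identical copies that can share reads, so the value of either is uncertain, and with 1 variance weight per group in voom *nspe-2* did not pass (adjusted p = 0.064). The invertebrate-type lysozyme *ilys-2* (chromosome IV, 2467678 to 2468879, plus strand) rose from 0.799 ± 0.293 to 7.23 ± 1.54 CPM (log2 fold change 3.18, SE 0.33, adjusted p = 0.0085). *hmit-1.1* (chromosome V, 18516789 to 18523875, plus strand), a proton-coupled myo-inositol transporter, stood at 7.71 ± 3.61 against 34.5 ± 2.27 CPM (log2 fold change 2.16, SE 0.32, adjusted p = 0.015). The other large rises were those of the lectin genes *clec-48* (1.77) and *clec-49* (1.65), the collagen genes *col-138* (1.77) and *col-73* (1.52), the carboxylesterase gene *cest-13* (1.58), the P-glycoprotein gene *pgp-9* (1.52), *F10A3.4* (1.47), which the table annotates to the innate immune response, and the uncharacterized *Y47D7A.13* (1.45). Their adjusted p lay between 0.0069 and 0.049.

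The largest fall by the same rule was that of *dpy-14* (chromosome I, 6843589 to 6845142, plus strand), a collagen gene of embryos and young larvae, at 20.1 ± 16 in controls and 0.830 ± 0.418 in treated libraries (log2 fold change -4.58, SE 0.91, adjusted p = 0.030). Its control libraries differed widely, at 2.81, 35 and 22.6. *drd-10* (-3.12), the collagen gene *dpy-17* (-2.45), *noah-1* (-2.27), which encodes a protein of the apical matrix under the cuticle, and *T02E9.5* (-2.40) fell likewise. These 5 genes no longer passed with limma on FPKM under either rescaling, and the range of their controls was wide throughout (*drd-10* 68.3 ± 49 against 7.87 ± 0.547 CPM, *noah-1* 24 ± 14.5 against 4.98 ± 1.12 CPM). Small heat shock genes fell with little spread in either group: *hsp-16.48* (chromosome V, 9088131 to 9088617, plus strand) stood at 7.43 ± 1.02 against 1.31 ± 0.372 CPM (log2 fold change -2.49, SE 0.27, adjusted p = 0.0087), *hsp-16.49* had a log2 fold change of -2.40 and *hsp-16.11* one of -2.41. Each of these 3 has a near-identical copy, so they are uncertain as single genes. The remaining large falls were those of *gst-35* (-2.80), a glutathione S-transferase gene, *C45B2.3* (-2.22), *F57H12.6* (-2.1) and *dao-2* (-2.07).

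Because the series asks about ER stress, the genes of the ER were examined first. The ER chaperone and unfolded protein response list did not pass: of 29 tested members, 0 rose and 1 fell, with a median log2 fold change of -0.12 (camera adjusted p = 0.12), and 0 rose and 1 fell adjusted over the list alone. DESeq2 called 0 rises and 4 falls. The 1 that fell was *fkb-3* (log2 fold change -0.94, SE 0.16, adjusted p = 0.018), an ER peptidyl-prolyl isomerase. *hsp-4* (chromosome II, 7350112 to 7352518, minus strand) had a log2 fold change of -0.07 (95% interval -0.54 to 0.41, adjusted p = 0.88). It fell past the threshold without control replicate 1 (-0.28, adjusted p = 0.036) and stood at 0.14 without control replicate 2, where it did not pass. Its partner *hsp-3* stood at 407 ± 80.2 against 386 ± 6.02 CPM (adjusted p = 0.80). Of the sensors and transcription factors of the response, *ire-1* (log2 fold change 0.10, adjusted p = 0.67), *atf-6* (-0.15, adjusted p = 0.61), *pek-1* (-0.43, adjusted p = 0.17) and *xbp-1* (0.27, adjusted p = 0.13) did not pass. Without control replicate 1, *xbp-1* (0.33) and *pek-1* (-0.57) passed in opposite directions, and the list as a whole passed downward, with 4 rising and 12 falling (median -0.21, camera adjusted p = 0.0043). Without control replicate 2 its median was -0.07, with 1 rising and 1 falling. The table counts whole genes, so the spliced form of *xbp-1* cannot be told from the unspliced one.

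ER-associated degradation genes, which clear misfolded proteins from the ER, passed upward as a list. Here, of 17 tested members, 3 rose and 0 fell, with a median of 0.25, or 0.13 without control replicate 1 (camera adjusted p = 0.0015, and adjusted p = 0.45 with an estimated correlation), and 6 rose and 0 fell adjusted over the list alone. The ubiquitin ligase gene *hrdl-1* stood at 115 ± 12 against 187 ± 4.65 CPM (log2 fold change 0.71, SE 0.10, adjusted p = 0.015) and *ufd-1*, of the complex that pulls proteins out of the membrane, at 77.5 ± 4.99 against 109 ± 3.71 CPM (log2 fold change 0.50, SE 0.09, adjusted p = 0.024), though *ufd-1* did not pass on FPKM rescaled to TPM (0.069). Genes of the translocon, signal peptide processing and N-glycosylation did not pass as a list (camera adjusted p = 0.92), and of 20 tested members, 0 rose and 1 fell, with 0 rising and 2 falling adjusted over the list alone; fry gave it the opposite direction. The faller was *sec-61.G* (log2 fold change -0.69, SE 0.09, adjusted p = 0.011), a subunit of the translocon. The *abu* and *pqn* genes, first described as raised when the unfolded protein response is blocked, had a median of 1.47 and passed upward (camera adjusted p = 1.5e-05, and adjusted p = 0.18 with an estimated correlation). In this list, of 17 tested members, 3 rose and 0 fell, and 9 rose and 0 fell adjusted over the list alone. They were scarce: *abu-7* stood at 0.113 ± 0.0463 against 0.884 ± 0.402 CPM and *abu-1* at 0.127 ± 0.0531 against 0.809 ± 0.208 CPM, and too few reached a mean of 1 FPKM for the list to be tested on that scale, where the pseudocount of 1 shrinks the fold changes of such genes (median 0.35 on FPKM rescaled to TPM). With 1 variance weight per group in voom neither gene passed (adjusted p = 0.19 and 0.15). Many *abu* and *pqn* genes are expressed in the pharynx and resemble each other in sequence, so single members are uncertain.

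**Figure D3:**
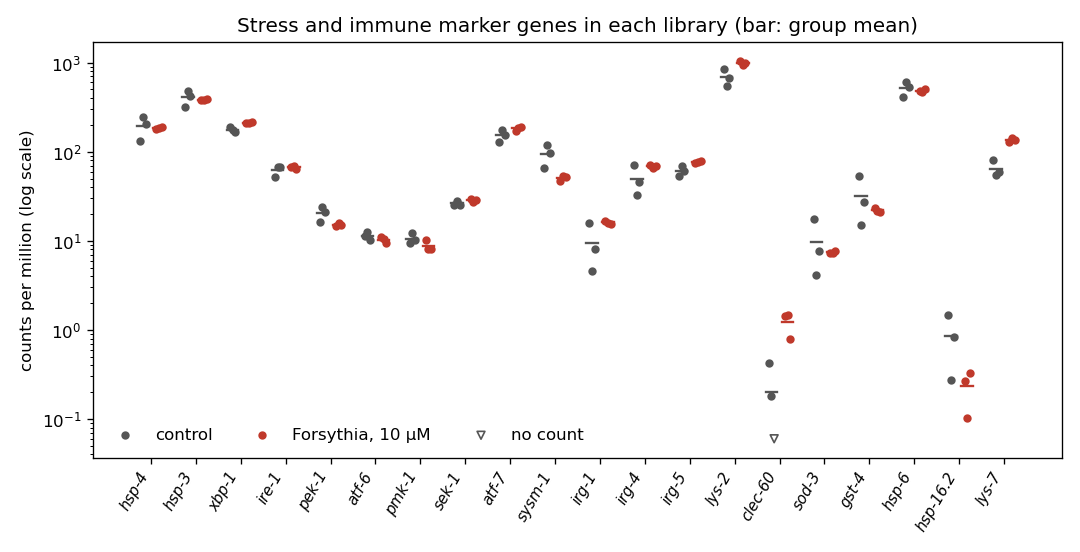
CPM on a log scale (y axis) of 20 stress and immune genes (x axis), with 1 point per library and a bar at the group mean of 3 libraries; an open triangle marks a library without a count. *hsp-4*, *hsp-3* and *hsp-6* overlap between groups, *lys-7* is higher and *sysm-1* lower in all 3 treated libraries.

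Immune effector genes rose in part. The p38 MAP kinase pathway, which controls much of the intestinal defence against *P. aeruginosa*, did not pass at the level of its own transcripts (camera adjusted p = 0.29). In it, of 22 tested members, 1 rose and 0 fell, with 2 rising and 0 falling adjusted over the list alone. The riser was *skn-1* (log2 fold change 0.54, SE 0.12, adjusted p = 0.043), a stress transcription factor gene, which did not pass on FPKM (adjusted p = 0.063). The SKN-1, mitochondrial unfolded protein response and oocyte and embryo lists also hold *skn-1*. The kinase genes *pmk-1* (10.6 ± 1.46 against 8.80 ± 1.14 CPM, adjusted p = 0.40) and *sek-1* (adjusted p = 0.57) and the transcription factor gene *atf-7* (adjusted p = 0.29) did not pass. The list of PMK-1-dependent effectors passed upward with a median of 0.29 (camera adjusted p = 4.8e-04, and adjusted p = 0.11 with an estimated correlation). Here, of 25 tested members, 3 rose and 1 fell, with 4 rising and 1 falling adjusted over the list alone. *clec-67* stood at 73.3 ± 5.01 against 172 ± 12.1 CPM (log2 fold change 1.23, SE 0.10, adjusted p = 0.0063) and *K08D8.5* at 23 ± 0.683 against 37.9 ± 0.621 CPM (log2 fold change 0.72, SE 0.10, adjusted p = 0.013). Against the direction of its list, *sysm-1* (T24B8.5), the effector most used as a reporter of PMK-1 activity, fell from 94.1 ± 27.3 to 50.6 ± 3.65 CPM (log2 fold change -0.90, SE 0.21, adjusted p = 0.043). With DESeq2's size factors in edgeR, or limma on FPKM rescaled to TPM, it no longer passed. *irg-4* (log2 fold change 0.46, adjusted p = 0.31), *irg-5* (0.33, adjusted p = 0.13), *lys-2* (0.51, adjusted p = 0.11) and *clec-60* (2.60, adjusted p = 0.15) did not pass edgeR's test with all 6 libraries. DESeq2 called *lys-2* (adjusted p = 0.030) and *clec-60* (0.035), and in the list 7 rises and 1 fall. All 4 passed upward without control replicate 1 (0.80, 0.24, 0.69 and 3.69), and *irg-5* also without control replicate 2 (0.43).

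Lysozymes, which break bacterial cell walls, had a median of 0.48 and passed upward (camera adjusted p = 2.6e-04, and adjusted p = 0.11 with an estimated correlation). Here, of 13 tested members, 3 rose and 0 fell, and 5 rose and 0 fell adjusted over the list alone. *lys-8* stood at 159 ± 17.9 against 289 ± 2.58 CPM (log2 fold change 0.86, SE 0.11, adjusted p = 0.011) and *lys-7* at 64.6 ± 13.6 against 136 ± 6.64 CPM (log2 fold change 1.08, SE 0.15, adjusted p = 0.013). C-type lectins, sugar-binding proteins many of which are secreted into the gut, had a median of 0.30, or 0.16 without control replicate 2 and 0.20 without Forsythia replicate 2 (camera adjusted p = 2.3e-04, and adjusted p = 0.082 with an estimated correlation). In this family, of 126 tested members, 15 rose and 7 fell, and 21 rose and 8 fell adjusted over the list alone. *clec-83* stood at 43.8 ± 1.41 against 96.2 ± 3.36 CPM (log2 fold change 1.14, SE 0.09, adjusted p = 0.0063). Caenopores, pore-forming antimicrobial proteins, did not pass as a list (camera adjusted p = 0.74), and of 17 tested members, 1 rose and 1 fell, with 1 rising and 2 falling adjusted over the list alone. Their median (-0.07, or 0.01 with size factors of FPKM, -0.21 with DESeq2, -0.35 without control replicate 2 and 0.02 without control replicate 3) and their camera test differed in sign. *spp-8* rose by 1.18 (adjusted p = 0.0063). Pathogen-response genes outside PMK-1 control passed upward, with a median of 0.35 (camera adjusted p = 0.0018, and adjusted p = 0.27 with an estimated correlation). That median was 0.07 on FPKM rescaled to TPM, 0.13 with size factors, 0.15 without control replicate 1, 0.23 without control replicate 3 and 0.17 without Forsythia replicate 3. Here, of 21 tested members, 3 rose and 0 fell, and 3 rose and 0 fell adjusted over the list alone. The 3 were *irg-7* (log2 fold change 1.18, SE 0.15, adjusted p = 0.010), *elt-2* (log2 fold change 0.97, SE 0.14, adjusted p = 0.013), which encodes the main transcription factor of the intestine, and *ZK6.11*. *irg-1*, a marker of blocked translation, stood at 9.49 ± 5.73 against 16 ± 0.685 CPM and did not pass (adjusted p = 0.29) except without control replicate 1 (1.34).

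Epidermal antimicrobial peptides moved the other way, with a median of -0.56 (camera adjusted p = 0.0023, and adjusted p = 0.76 with an estimated correlation). Of 39 tested members, 0 rose and 5 fell with edgeR, 0 rose and 9 fell with DESeq2, and 0 rose and 6 fell adjusted over the list alone. At an unadjusted p under 0.05, 0 rose and 11 fell. *nlp-24* stood at 121.2 ± 29.9 against 54.3 ± 1.26 CPM (log2 fold change -1.16, SE 0.17, adjusted p = 0.015) and *cnc-2* at 8.70 ± 1.80 against 2.57 ± 0.698 CPM (log2 fold change -1.76, SE 0.27, adjusted p = 0.015). These genes also separated the controls, with a median difference of -1.35 between controls 2 and 1, and the list lost its call without control replicate 1 (median -0.10, camera adjusted p = 0.30). Genes of the intracellular pathogen response, which microsporidia and viruses switch on, had a median of 0.26 (camera adjusted p = 0.031, and adjusted p = 0.52 with an estimated correlation). In this list, of 24 tested members, 1 rose and 0 fell, and 1 rose and 0 fell adjusted over the list alone. The riser was *pnp-1* (log2 fold change 0.60, SE 0.10, adjusted p = 0.019), a purine nucleoside phosphorylase gene, and *pals-23* did not pass (adjusted p = 0.10, but 0.0086 with DESeq2). That 1 call does not show that the response as a whole was raised. Of 13 tested *pals* genes 0 rose and 0 fell, with a median of 0.01. The call of this list ended without control replicate 2 (0.26) or 3 (0.070), without Forsythia replicate 1 (0.14) or 2 (0.17), and with size factors of FPKM (0.10), all adjusted p from camera. Its median was 0.11 with DESeq2 and, with 1 library left out, ran from 0.04 without Forsythia replicate 2 to 0.51 without control replicate 1.

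Stress pathways outside the ER were compared next. In the cytosolic heat shock list, of 23 tested members, 0 rose and 6 fell, with a median of -0.25, or -0.13 on FPKM rescaled to TPM and -0.06 with size factors, where 6 fell as well (camera adjusted p = 6.5e-06, and adjusted p = 0.082 with an estimated correlation), and 0 rose and 8 fell adjusted over the list alone. Besides the *hsp-16* genes, the fallers were *F44E5.4* and *F44E5.5*, near-identical *hsp-70* genes, and *bag-1*. *hsp-16.2* stood at 0.860 ± 0.603 against 0.233 ± 0.118 CPM and did not pass (adjusted p = 0.17), except without control replicate 2 (-2.30, adjusted p = 0.045). In the mitochondrial unfolded protein response list, of 20 tested members, 1 rose and 1 fell (camera adjusted p = 0.22), with 1 rising and 1 falling adjusted over the list alone, and its marker *hsp-6* stood at 519 ± 102 against 485 ± 16 CPM (adjusted p = 0.75). Antioxidant enzymes had a median of -0.34 (camera adjusted p = 0.033, and adjusted p = 0.42 with an estimated correlation). Here, of 25 tested members, 2 rose and 3 fell, and 2 rose and 7 fell adjusted over the list alone. *gpx-1*, a glutathione peroxidase gene (log2 fold change -1.24, SE 0.15, adjusted p = 0.0096), and *msra-1*, a methionine sulfoxide reductase gene (log2 fold change -1.08, SE 0.12, adjusted p = 0.0087), fell, and *sod-3* did not pass (adjusted p = 0.66). The call of this list ended on FPKM rescaled to TPM (camera adjusted p = 0.073) or by size factors (0.072), without control replicate 1 (0.15) and without Forsythia replicate 1 (0.065) or 2 (0.059). Its median was -0.19 with size factors and -0.01 without control replicate 1. In the autophagy and lysosome list, of 42 tested members, 0 rose and 1 fell (camera adjusted p = 0.31), with 0 rising and 1 falling adjusted over the list alone; the faller was *epg-2* (log2 fold change -1.49, SE 0.18, adjusted p = 0.010), a gene of selective autophagy in embryos. Without control replicate 2 that list passed upward (camera adjusted p = 0.019).

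Among detoxification genes, ABC efflux pumps had the smallest p as a list. Their median was 0.44, or 0.28 on FPKM rescaled to TPM (camera adjusted p = 1.5e-05, and adjusted p = 0.082 with an estimated correlation). In this family, of 37 tested members, 5 rose and 0 fell, and 6 rose and 0 fell adjusted over the list alone. *pgp-1* (chromosome IV, 12591704 to 12599169, minus strand) stood at 3.95 ± 1.75 in controls and 17.9 ± 2.53 in treated libraries (log2 fold change 2.18, SE 0.31, adjusted p = 0.013), and *pgp-9* at 14.5 ± 1.66 against 41.6 ± 3.56 CPM (log2 fold change 1.52, SE 0.14, adjusted p = 0.0069). The other detoxification lists did not pass. Of 57 cytochrome P450 genes, 1 rose and 2 fell (camera adjusted p = 0.65), with 1 rising and 2 falling adjusted over the list alone, their median and mean differing in sign, and *cyp-13B1* fell by 2.62 on the log2 scale (adjusted p = 0.016). Of 43 glutathione S-transferase genes, 0 rose and 3 fell (camera adjusted p = 0.23, or 0.045 downward without control replicate 2), with 0 rising and 4 falling adjusted over the list alone. Their median of -0.21 became -0.07 with size factors of FPKM, 0.06 without control replicate 1, with 8 rising and 5 falling, and -0.32 without control replicate 2. Of 59 UDP-glucuronosyltransferase genes, 2 rose and 1 fell (camera adjusted p = 0.23, or 0.024 upward on FPKM rescaled to TPM), with 2 rising and 1 falling adjusted over the list alone, and *ugt-63* had a log2 fold change of -1.01 (adjusted p = 0.012). In the SKN-1 and phase II list, of 29 tested members, 1 rose and 1 fell (camera adjusted p = 0.63), with 1 rising and 4 falling adjusted over the list alone, and its marker *gst-4* stood at 32 ± 19.7 against 22.1 ± 1.38 CPM (adjusted p = 0.46).

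Targets of DAF-16, the transcription factor of low insulin signalling, were compared in 2 lists, those raised and those lowered when insulin signalling is low, and both passed upward with all 6 libraries. Of those raised in low insulin signalling, 5 of 28 rose and 0 fell, with a median of 0.21 (camera adjusted p = 0.0024, and adjusted p = 0.27 with an estimated correlation), and 7 rose and 0 fell adjusted over the list alone. Without control replicate 2 the median was -0.00, with 7 rising and 3 falling, and without control replicate 1 it was 0.39, with 12 rising and 0 falling. The leading members were *lys-7* and *lys-8*, which the lysozyme list also holds. Of those lowered in low insulin signalling, 3 of 19 rose and 2 fell, with a median of 0.32 (camera adjusted p = 0.034, and adjusted p = 0.27 with an estimated correlation), and 5 rose and 2 fell adjusted over the list alone. *dod-19* rose by 0.97 and *pes-2.1* fell by 1.46 on the log2 scale (adjusted p = 0.0069 and 0.015). The second list lost its call without control replicate 1 (camera adjusted p = 0.17) and with size factors of FPKM (0.065).

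Yolk, ribosomal and lipid genes were compared next. The vitellogenin list had a median of 0.66 (camera adjusted p = 6.2e-04, and adjusted p = 0.47 with an estimated correlation). In it, of 7 tested members, 2 rose and 0 fell, and 3 rose and 0 fell adjusted over the list alone. *vit-2* (chromosome X, 5101042 to 5106169, plus strand) stood at 7690.1 ± 2316 in controls and 17152 ± 1493 in treated libraries (log2 fold change 1.16, SE 0.23, adjusted p = 0.028) and *vit-6* at 7896 ± 2537 against 16181 ± 1278 CPM (log2 fold change 1.04, SE 0.24, adjusted p = 0.043). *vit-6* did not pass on FPKM rescaled to TPM (adjusted p = 0.056). The controls differed here too, by a median of 1.16 between controls 2 and 1, and the list's median was 0.32 without control replicate 1 and 1.02 without control replicate 2. Cytosolic ribosomal protein genes had a median of 0.27 (camera adjusted p = 1.7e-07, and adjusted p = 0.51 with an estimated correlation). Here, of 82 tested members, 5 rose and 0 fell, and 19 rose and 1 fell adjusted over the list alone. The counts were 17 and 3 on FPKM rescaled to TPM, 25 and 2 with DESeq2, 49 and 3 without control replicate 1, and 9 and 3 without control replicate 2. *rpl-7* (log2 fold change 0.52, SE 0.11, adjusted p = 0.036) and *rpl-19* (log2 fold change 0.52, SE 0.12, adjusted p = 0.042) were the leading members, and *rpl-19* did not pass on FPKM (adjusted p = 0.057). The remaining lists did not pass. In the fatty acid and lipid list, of 42 tested members, 3 rose and 2 fell (camera adjusted p = 0.36), with 5 rising and 2 falling adjusted over the list alone, the median (0.03, or 0.15 with size factors of FPKM and 0.10 without control replicate 2) and mean (-0.06) differing in sign, and *fat-2*, a fatty acid desaturase gene, stood at 239 ± 27.3 against 462 ± 8.29 CPM (log2 fold change 0.95, SE 0.11, adjusted p = 0.0093). In the oxidative phosphorylation list, of 46 tested members, 0 rose and 1 fell (camera adjusted p = 0.32), with 0 rising and 0 falling adjusted over the list alone; the faller was *cox-19* (adjusted p = 0.046). Of 33 proteasome genes, edgeR called 0 and DESeq2 2, with 3 at an unadjusted p under 0.05 in edgeR (camera adjusted p = 0.35, or 0.031 upward without control replicate 2), and 0 rose and 0 fell adjusted over the list alone.

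As lists, cuticle collagen genes passed upward and moulting genes downward. Collagens had a median of 0.42 (camera adjusted p = 1.5e-04, and adjusted p = 0.76 with an estimated correlation). The *col* genes took 9.31%, 4.95% and 5.80% of control counts and 5.14%, 5.24% and 5.68% of treated counts, so control 1 had the largest share. The list's median log2 CPM relative to the control mean was likewise higher in control 1 (0.69) than in treated libraries (0.48, 0.63 and 0.55). In this family, of 142 tested members, 8 rose and 3 fell, and 12 rose and 4 fell adjusted over the list alone. Without control replicate 1 the collagen median was 0.90, with 72 rising and 13 falling, and without control replicate 2 it was 0.17, with 11 rising and 4 falling. On FPKM rescaled to TPM 16 collagens rose and 2 fell, and with DESeq2 28 rose and 9 fell. *col-10* rose by 0.97 (adjusted p = 0.021) and *col-135* had a log2 fold change of -0.88 (adjusted p = 0.015). Moulting and oscillating cuticle genes had a median of -0.40 (camera adjusted p = 0.030, and adjusted p = 0.27 with an estimated correlation). Of 52 tested members, 0 rose and 5 fell with edgeR, 1 rose and 11 fell with DESeq2, 3 rose and 13 fell at an unadjusted p under 0.05, and 0 rose and 6 fell adjusted over the list alone. With limma on FPKM rescaled to TPM, and with size factors, 1 rose and 1 fell. The median of this list was -0.13 without control replicate 1, where 2 rose and 12 fell, and 1 rose and 9 fell without control replicate 2. *fbn-1* stood at 8.23 ± 3.58 against 1.80 ± 0.235 CPM (log2 fold change -2.19, SE 0.36, adjusted p = 0.018) and *wrt-10* at 5.25 ± 2.17 against 1.43 ± 0.475 CPM (log2 fold change -1.87, SE 0.41, adjusted p = 0.039). Between controls 2 and 1 the median difference was -1.26 for collagens and -0.48 for moulting genes, and the moulting list lost its call without Forsythia replicate 2 (camera adjusted p = 0.059).

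Marker lists of several tissues passed upward. Oocyte and embryo genes had a median of 0.49, or 0.32 without control replicate 1 (camera adjusted p = 7.0e-13, and adjusted p = 0.44 with an estimated correlation). In this list, of 34 tested members, 9 rose and 0 fell, and 17 rose and 0 fell adjusted over the list alone. On FPKM 3 rose when rescaled to TPM and 16 with size factors, and with edgeR 20 rose without control replicate 1 and 24 without control replicate 2, with 0 falling in each. *cpg-2*, an eggshell proteoglycan gene, stood at 1472 ± 127 against 2774 ± 125 CPM (log2 fold change 0.91, SE 0.11, adjusted p = 0.010), and *perm-4*, of the eggshell's permeability barrier, at 1177 ± 85.4 against 1875 ± 143 CPM (log2 fold change 0.67, SE 0.11, adjusted p = 0.019). Body wall muscle genes had a median of 0.44 (camera adjusted p = 1.9e-08, and adjusted p = 0.36 with an estimated correlation). Here, of 26 tested members, 8 rose and 1 fell, and 14 rose and 1 fell adjusted over the list alone. The myosin heavy chain gene *unc-54* stood at 773 ± 60.9 against 1752 ± 166 CPM (log2 fold change 1.18, SE 0.12, adjusted p = 0.0082) and the paramyosin gene *unc-15* at 580.2 ± 60.6 against 1155 ± 86.9 CPM (log2 fold change 0.99, SE 0.12, adjusted p = 0.010). Pharynx genes had a median of 0.27, or 0.50 on FPKM rescaled to TPM, 0.53 with size factors, 0.71 without control replicate 1 and 0.46 without control replicate 3 (camera adjusted p = 0.0025, and adjusted p = 0.44 with an estimated correlation). In this list, of 19 tested members, 4 rose and 0 fell, and 4 rose and 1 fell adjusted over the list alone. The pharyngeal myosin genes *myo-1* and *myo-2* rose by 1.5 and 1.5 (adjusted p = 0.013 and 0.0069). Intestine genes had a median of 0.40 (camera adjusted p = 1.8e-06, and adjusted p = 0.17 with an estimated correlation). Here, of 26 tested members, 7 rose and 1 fell, and 10 rose and 1 fell adjusted over the list alone. The intermediate filament genes *ifc-2* and *ifb-2* rose by 1.0 and 0.84 (adjusted p = 0.0077 and 0.0091). Between controls 2 and 1 the medians of these 4 lists differed by 0.61, -0.51, -0.91 and 0.17.

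Sperm genes passed upward as a list, with a median of 0.15, or 0.35 on FPKM rescaled to TPM, 0.39 with size factors and 1.02 without control replicate 1 (camera adjusted p = 0.045, and adjusted p = 0.82 with an estimated correlation). Of 62 tested members edgeR called 0 and DESeq2 1, with 1 at an unadjusted p under 0.05 in edgeR, and 0 rose and 0 fell adjusted over the list alone. Without control replicate 1, 33 rose and 0 fell with edgeR, and 31 rose with DESeq2. The members with the smallest p were *spe-41* (adjusted p = 0.056, but 0.0028 with DESeq2) and *gsp-3* (adjusted p = 0.33). The difference of -2.55 between controls 2 and 1 exceeded the difference between the groups, and the list turned to the opposite direction without control replicate 2 (median -0.28, camera adjusted p = 0.25). Its call also ended without control replicate 3 (0.066, median -0.03), without Forsythia replicate 2 (0.055) or 3 (0.061) and with size factors of FPKM (0.065). Of 10 male-enriched genes and spermatogenesis kinases edgeR called 0 and DESeq2 1, which fell, with 3 at an unadjusted p under 0.05 in edgeR (camera adjusted p = 0.12), and 0 rose and 0 fell adjusted over the list alone. In the list of the mitotic germline and germ granules, of 33 tested members, 2 rose and 0 fell (camera adjusted p = 0.14, or 0.0023 upward without control replicate 2), with 5 rising and 1 falling adjusted over the list alone, and *prg-1*, a Piwi gene, rose by 0.46 (adjusted p = 0.030, but 0.052 on FPKM). In the hypodermis list, of 23 tested members, 1 rose and 1 fell (camera adjusted p = 0.92), with 2 rising and 2 falling adjusted over the list alone, and its median and its camera test differed in sign. Of 65 neuronal genes, 3 rose and 1 fell (camera adjusted p = 0.26, or 0.0034 without control replicate 1 and 0.045 on FPKM rescaled to TPM, both upward), with 3 rising and 1 falling adjusted over the list alone; the peptide-processing gene *egl-21* stood at 28.3 ± 4.28 against 46.8 ± 1.91 CPM (adjusted p = 0.023). Of 14 coelomocyte and excretory cell genes, 0 rose and 1 fell, *exc-9* (camera adjusted p = 0.55), with 0 rising and 1 falling adjusted over the list alone. Of 68 histone genes, 1 rose and 4 fell (camera adjusted p = 0.14), with 1 rising and 4 falling adjusted over the list alone. The linker histone gene *his-24*, which the name pattern of that list also takes, fell from 163 ± 60.9 to 52.9 ± 3.42 CPM (log2 fold change -1.62, SE 0.26, adjusted p = 0.017). Core histone mRNAs mostly lack a poly(A) tail and their genes are near-identical, so poly(A)-selected libraries count them poorly.

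Across the 41 lists, 22 passed camera with its preset correlation, 18 upward and 4 downward. Some lists share members, such as *skn-1*, *clec-67*, *lys-7*, and *elt-2* and *pgp-1*, which the intestine list also holds, so the lists are not independent. With a correlation estimated from these libraries 0 passed (smallest adjusted p = 0.082, smallest unadjusted p = 0.0037). With fry, which asks whether a list's genes move on balance in one direction, 10 passed: the *abu* and *pqn* genes, PMK-1-dependent effectors, other pathogen-response genes, lysozymes, C-type lectins, DAF-16 targets lowered in low insulin signalling, ABC efflux pumps and intestine genes upward, and the cytosolic heat shock and moulting lists downward.

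**Figure D4:**
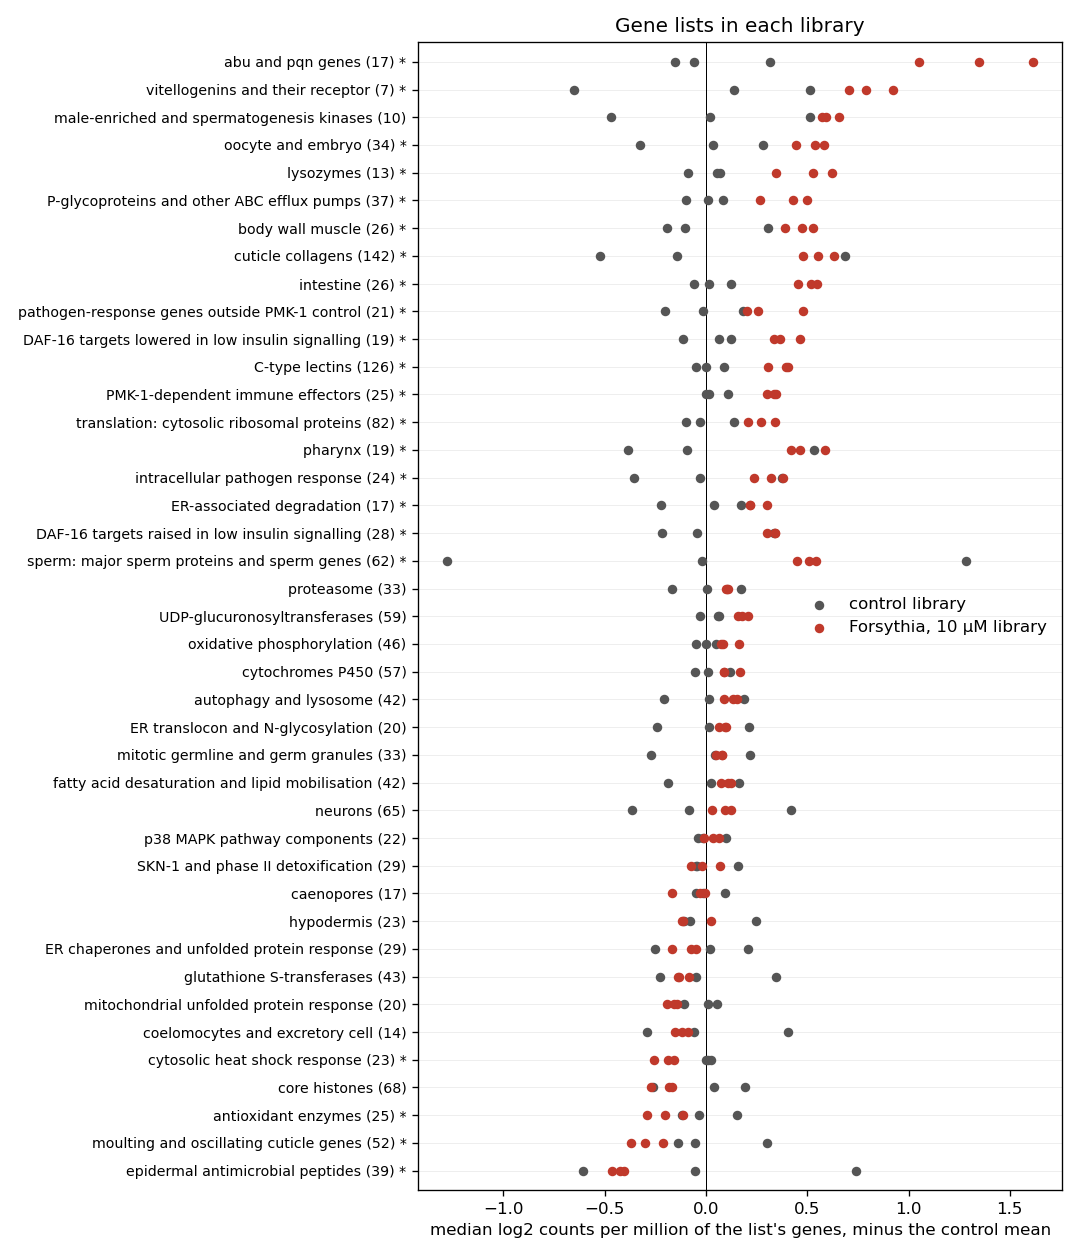
Median log2 CPM of each list's tested genes relative to the control mean (x axis), for the 41 lists (y axis, number of tested genes in brackets), with 1 point per library; asterisks mark lists past camera with the preset correlation. In many lists, marked ones included, the controls are spread more widely than the distance between the groups' means. Among these are the sperm, collagen, vitellogenin, epidermal peptide, pharynx, oocyte and embryo, body wall muscle and intracellular pathogen response lists, and the DAF-16 targets raised in low insulin signalling.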

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

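Robust edgeR, voom with group weights, removal of abundant genes, other similarity measures and DESeq2 with a library left out were chosen after seeing the data, and limma on log2(FPKM + 1), which the plan named, was listed as an alternative then. The 1128 calls became 2136 with DESeq2 (668 of them with a log2 fold change of at least 1, against 408), 590 without a count filter (226), and 8736 with limma and array quality weights; the cause was not tested. Counts from the other limma fits lay between 849 and 1524. At a log2 fold change of at least 1 they were 93 with a pseudocount of 5, 192 without a filter, 190 at a mean of at least 5 FPKM, 219 with size factors and 227 with quantile normalisation, and between 279 and 445 in the rest; apart from the pseudocount, which shrinks fold changes by its construction, the cause was not tested. All main calls that a setting tested kept their sign in it. With 1 library left out, edgeR called between 0 and 4619 genes (0 to 1179 with a log2 fold change of at least 1) and DESeq2 between 891 and 4584 (437 to 1186); without control replicate 2 DESeq2 called 3025 (820). Whether replicate numbers pair the libraries is not known. Deviations from the group means correlated at 0.035, 0.014 and 0.0026 between libraries of the same number. That is no sign of pairing, but with treated libraries so alike it cannot exclude pairing. With a block edgeR called 437 (232) and limma 996. In either, 0 cytosolic ribosomal protein genes rose, against 5 without a block in edgeR and 25 in DESeq2. Among gene lists, 22 passed camera, 0 with an estimated correlation and 10 with fry, which does not compare a list with other genes; the cause was not tested. With 1 library left out, the adjusted p of the sperm list ranged from 2.5e-09 without control replicate 1 to 0.25 without control replicate 2, where its direction reversed. Of 73 called genes that are named, 73 passed with DESeq2, which also called 4 others that are named, and 51 without a count filter. *ire-1*, not called, passed in the opposite direction with array quality weights (-0.16); the cause was not tested. Correlations between libraries, computed also with other pseudocounts and on log2 CPM, put controls 1 and 2 between 0.931 and 0.953. Depth limits genes at low counts such as *abu-7* and *abu-1*, under 1 CPM in both groups.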

Other observations

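All tests in this part were chosen after the results had been seen. Transcripts first made by the early embryo itself were lower in treated libraries. A list of zygotic early-embryo genes (the *sdz* and *vet* genes and regulators of endoderm and mesoderm such as *end-1* and *tbx-35*) was written after 4 of its members had appeared among the falls. Of 45 tested members 0 rose and 18 fell, and 43 had a lower mean in treated libraries, with a median log2 fold change of -1.33 (-1.02 on FPKM rescaled to TPM, -0.91 with size factors). Without the 4 members seen first, 14 of 41 fell and 0 rose, with a median of -1.25 (-0.83 on FPKM rescaled to TPM, -0.73 with size factors; camera p = 7.7e-04 with an estimated correlation, from edgeR's log2 CPM, not adjusted). Mitochondrial ribosomal protein genes fell in 16 of 71 cases and rose in 0 (median -0.34), the *skr* genes of ubiquitin ligase complexes fell in 9 of 19 and rose in 0 (median -0.69), and of 252 F-box genes 46 fell and 3 rose (median -0.45, but -0.21 on FPKM rescaled to TPM and -0.16 with size factors). Among controls the library scores of the *skr* and F-box genes ranged over 0.798 and 0.448, more than the gaps of 0.685 and 0.418 between the groups. Of 12 osmotic stress genes, listed because *hmit-1.1* rose, 2 rose and 0 fell (median 0.05).

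Of 988 Gene Ontology terms, 46 passed camera with its preset correlation and 0 with an estimated one. The smallest p was that of myosin filament, with 5 of 10 genes rising and 0 falling (median 0.66). Among falling terms it was that of cullin family protein binding, with 0 of 26 rising and 10 falling (median -0.40). The terms named next were picked for their bearing on immunity and stress. Innate immune response moved up, with 32 of 251 genes rising and 10 falling (median 0.25), and unfolded protein binding moved down, with 0 of 55 rising and 8 falling (median -0.18). Unlike the autophagy and lysosome list, which did not pass, the term autophagy moved down, with 1 of 53 rising and 11 falling (median -0.17). The term lysosome moved up, with 10 of 103 rising and 2 falling (median 0.15). Of 120 KEGG pathways 3 passed with the preset correlation, ABC transporters and phagosome upward and protein export downward, and 0 with an estimated one.

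The 1128 genes that differed between the groups were weighed first, because the controls differed so much among themselves. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many genes, and the highest of the others gave 1. With 10 splits a share under 0.05 cannot be reached. The difference between the groups shared a squared cosine of 0.0348 with that between controls 1 and 2, which argues against treated libraries lying farther along the axis that separates those controls. After removal of ribosomal RNA and the 100 most abundant genes 99.6% of the calls still tested stayed, but the median log2 fold change hardly moved (-0.0360 to -0.0355), so this removal says nothing of other scalings, which changed the split into rises and falls. In limma, size factors moved the median of FPKM from -0.139 to -0.0035, and quantile normalisation moved it to 0.019. Of 1061 main calls tested, 1012 and 1005 passed there, against 874 on FPKM as deposited and 781 rescaled to TPM. All 1061 kept their sign in each, but median shifts this small could turn few signs, so no support is read from that. The numbers that passed argue against the choice among these scalings as the cause of the difference as a whole. An error that all of them share was not tested, and the split into rises and falls stays open. A difference in culture or handling between the groups, which was not tested, stays open too.

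The lower zygotic transcripts are hard to explain by less RNA of oocytes and embryos together. That needs a negative median of the oocyte and embryo list, which was 0.49. With 1 library left out it lay between 0.32 (without control replicate 1) and 0.65 (without control replicate 2). That list's rise is itself unsure (adjusted p = 0.44 with an estimated correlation), and its control scores ran from -0.32 to 0.28, against 0.44 to 0.58 in treated libraries. It scores oocyte and embryo genes together, so less embryo RNA beside more oocyte RNA stays open. Of 54 genes of the Gene Ontology term embryo development, 1 rose and 8 fell (median -0.81). Of 280 genes of the term embryo development ending in birth or egg hatching, 13 rose and 6 fell (median 0.07). The control scores of the zygotic list spanned 0.0827 of the gap between the groups, which argues against the axis that separates the controls. The groups may differ in the number or age of the embryos held in the worms, or in worm age at harvest. For 0 of the 6 libraries do the labels give an age, stage or time, so these cannot be told apart from an effect of the agent.

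Immune effector transcripts were weighed against the intestine list, whose median was 0.40. Of 173 immune members 23 had a 95% interval wholly above that median and 17 one wholly below 0, against 8 and 1 of the 26 intestine members (two-sided Fisher's exact p = 0.038 and 0.48, or 0.075 for the smaller when both are counted). The intestine members themselves spread that widely, so a larger share of intestinal RNA cannot be told apart from a change in immune genes. The upper bound of the *hsp-4* change was 0.41 (1.33-fold), and 0.57 at most with 1 library left out, which argues against a doubling of this transcript at harvest, but says nothing of earlier times or of *xbp-1* splicing. An effect of the agent on immune genes, by way of ER stress or by another route, stays open. So do a larger intestinal share and differences in age or culture.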
